A study of Mus musculus with 15 samples.

How the data were processed

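RNA sequencing of 15 mouse cultures was re-examined from the 2 tables that were deposited for the series. The WT and KO groups form the knockout experiment, and the SC, SCR and SCRP groups form the pterosin B experiment, with 3 libraries in each of the 5 groups. Per the labels' protocols, RNA was depleted of ribosomal RNA and made into directional libraries from 500 ng of total RNA. Genome build GRCm38 (mm10) is given per the submitters' processing notes. The aligner, the counting program, their versions and the strand that was counted are not given in the sources used here. Some text of the series record speaks of embryonic livers, while the labels and protocols of all 15 samples name bone marrow monocytes, and the labels were used.

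The table of the pterosin B experiment lists 41819 genes, of which 21653 had no read in any library. Its deposited counts are whole exon reads per gene, with unique exon reads and intron reads beside them, per the file headers. Of the deposited counts between 1 and 39, from 75.3% to 79.0% per library were even, as when both reads of a pair are counted, against 45.5% to 50.7% in the knockout experiment. The deposited RPKM values are reads scaled for exon length and library total as the authors computed them, per the file headers. The deposited p-values and the p-values after false discovery rate correction come from a test with tagwise dispersions that the authors call EDGE, per the file headers. The deposited score of the authors' test is a signed fold value, with a negative fold for a fall in the second group, per the file headers. Other deposited values are gene coordinates, exon lengths and the authors' normalized group means, per the file headers. A further 174 per-sample columns, mostly repeats of these values and read totals of other gene parts, were not used here.

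The knockout table holds only 2275 genes. Every one of them has an authors' false discovery rate under 0.05 and an authors' fold of at least 2, with 1053 higher and 1222 lower in KO, so genes that did not move are not in it. This differs from what was planned for a full table: TMM factors over such a list would treat changed genes as the stable part of the library. Library totals were therefore recovered from the deposited counts, exon lengths and RPKM, and no scaling factors were applied. The resulting log2 fold changes differed from the authors' deposited fold by a median of -0.03 over 783 genes with at least 200 reads on average, and 0 genes differed in direction. Of the listed genes, 2247 have a name in the full table.

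Gene positions were compared with GENCODE mouse release 21 on GRCm38. All 41819 gene identifiers of the full table were found there, and 100.0% had the same start and end once starts were counted from 1. In the knockout table, 2228 of 2247 genes (99.2%) had equal positions. Overlapping genes were taken from the same annotation, and Rps18 was compared with its copy Gm10260 with BLAST 2.17.0.

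Counts were tested with the edgeR 4.0.16 quasi-likelihood method in R 4.3.3 after filterByExpr and, in the pterosin B experiment, TMM scaling. The 9 libraries of that experiment shared 1 fit with 6 residual degrees of freedom and a common dispersion of 0.0072. The filter left 13650 genes. The knockout fit had 4 residual degrees of freedom, a common dispersion of 0.00302 and 1773 genes, with 502 listed genes too low to test. P-values were adjusted with the Benjamini-Hochberg method, a gene passed at an adjusted p under 0.05, and no minimum fold was set. These tests are two-sided. CPM, counts scaled to library size, were computed with TMM-scaled totals in the pterosin B experiment and with the recovered totals in the knockout experiment. Where SCR levels are set against WT and KO levels in the chromosome 17 region, CPM of both experiments use the totals implied by RPKM, without TMM. A fold against a group with no read is given as a lower bound, computed with a floor of 3 counts per library. Floors cover counting error only, while SD and SE values include the spread between libraries. Tables were handled with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and plots were drawn with matplotlib 3.10.9.

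The comparisons, the tests, the gene lists, the rule for named genes and most alternative settings were fixed before the data were examined. The 28 lists with 536 entries are osteoclast differentiation, acid secretion, cell fusion, podosome and actin, anti-osteoclastogenic regulators, secreted osteoclast coupling factors, monocyte and macrophage, dendritic cell and MHC class II, neutrophil, lymphoid, erythroid and megakaryocyte, mast cell and basophil, stromal and osteoblast, cell cycle, interferon response, NF-kB and inflammation, SIK and CRTC components, CREB and CRTC targets, oxidative phosphorylation, glycolysis and hypoxia, NRF2 and oxidative stress, unfolded protein and integrated stress, heat shock, cholesterol synthesis, LXR and lipid handling, lysosome, xenobiotic and AHR, and p53 and apoptosis. Each was tested with camera of limma 3.58.1 at a preset correlation of 0.01 and again with an estimated correlation, and with fry, with adjustment over the 28 lists. In the knockout table, camera has no unchanged genes to compare with. There, the split of a list's genes into higher and lower was compared with that of the other listed genes by a two-sided Fisher exact test, adjusted over the lists. Genes named are Sik3, the 8 largest rises and the 8 largest falls that pass, change at least 2-fold, average at least 8 CPM and do not overlap between groups, up to 3 members of each list with the smallest adjusted p, and textbook osteoclast markers. Predicted genes and receptor segments were left out. For SCRP against SC only 7 osteoclast genes are named. Genes outside the rule are marked where they appear, and some genes the rule takes are not reported here.

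Responses were compared across genes with Pearson and Spearman correlations, and shared genes with Fisher exact tests over the 1667 listed genes tested in both experiments. RANKL and pterosin B responses share the SCR libraries, so their correlation was set against 100 simulations of unchanged groups. The tests were checked on simulated data in which 200 genes had been changed. For SCR against SC, with 13369 genes, 65.2% of the 1.5-fold, 83.1% of the 2-fold and 86.7% of the 4-fold changes were recovered, with 11 false calls. For SCRP against SCR, with 13369 genes, the shares were 58.6%, 84.1% and 89.6%, with 6 false calls. For SCRP against SC, with 13380 genes, they were 64.8%, 76.7% and 94.2%, with 12 false calls. For KO against WT, with 1720 genes, they were 73.5%, 69.7% and 93.9%, with 7 false calls. In each simulated comparison with lists, camera called the changed list and 0 of the unchanged lists. Simulated genes varied independently of each other, so this does not check camera on lists whose members are correlated.

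Alternative settings were DESeq2 1.42.0 size factors, the DESeq2 Wald test, no low-count filter, a minimum fold of 2, a replicate block, fits of only the groups compared, an 8 CPM minimum for correlations, an estimated list correlation, and leaving out each library in turn for counts of calls and named genes. Halved counts, unique reads, TMM factors over the listed genes, removal of a chromosome 17 region, left-out library versions of all correlations, a paired fit of only SCR and SCRP, and the 8 CPM and block versions of the comparison of KO with RANKL were added after the values had been seen. A change of pseudocount was planned only for normalized values and was not run, since counts were available. Replicate numbers may pair SCR with SCRP, a reading of the data that the labels do not state. Deviations from the group means correlated by 0.251, 0.226 and 0.146 between SCR and SCRP libraries of the same number, against -0.172 to -0.043 for the other pairs of these groups. No other comparison had every correlation over 0.1. Deviations within a group cancel out, so positive values at the same number push those of the other pairs down. Pairing was therefore not established. The fit without a block was kept as planned.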

Results

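Gene expression was measured by RNA sequencing in 15 cultures of mouse bone marrow monocytes, precursors that fuse into bone-resorbing osteoclasts under RANKL, the cytokine that drives their differentiation. In the knockout experiment, 3 wild-type libraries (WT) stood against 3 libraries with a deletion of Sik3 in the osteoclast lineage (KO), where Cre is expressed from the Rank locus. Both groups were kept in M-CSF, a macrophage growth factor, for 2 days and then given RANKL with M-CSF for 2 days, each at 50 ng/ml. In the pterosin B experiment, 3 libraries had vehicle and no RANKL (SC), 3 had RANKL for 3 days (SCR), and 3 had RANKL with pterosin B at 300 µM (SCRP). All of them had M-CSF at 50 ng/ml, alone for the first 2 days. How long SC was kept after those days is not stated in the sources used here. Pterosin B is a bracken fern compound used as an inhibitor of SIK3 signalling, SIK3 being a salt-inducible kinase.

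Reads in the table ranged from 40152624 to 48431715 in SC, from 37138648 to 49610156 in SCR and from 40338706 to 49927591 in SCRP. The library totals implied by the deposited RPKM ranged from 22358396 to 25405494 in WT and from 21267111 to 25932103 in KO. The genes listed in the knockout table took 2032475 to 2307420 reads in WT and 2436095 to 3041861 in KO. The labels do not say that the 3 libraries of a group come from separate animals, so all p-values measure only the spread between these samples.

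Sik3 (ENSMUSG00000034135, GRCm38 chromosome 9, 46012820 to 46224194) was lower in each KO library than in each WT library. The WT libraries had 58.3, 59.4 and 56.0 CPM and the KO libraries 23.9, 17.6 and 19.4 CPM. The mean fell from 57.9 ± 1.74 to 20.3 ± 3.25 CPM (SD, n = 3), a log2 fold change of -1.52 ± 0.08 (SE) with adjusted p = 5.31e-14 by edgeR quasi-likelihood with Benjamini-Hochberg adjustment. Counts cover the whole gene, so reads of a transcript without the floxed part are included. The study listed Sik3 because it differed between these libraries, so the adjusted p for KO against WT is not independent evidence. In the pterosin B experiment, Sik3 stood at 51.2, 54.8 and 53.01 CPM in SC, at 67.0, 64.1 and 65.1 CPM in SCR, and at 52.1, 49.4 and 52.1 CPM in SCRP. It rose with RANKL by a log2 fold change of 0.30 (adjusted p = 9.59e-05) and was lower with pterosin B by -0.35 (adjusted p = 5.31e-05).

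**Figure D1:**
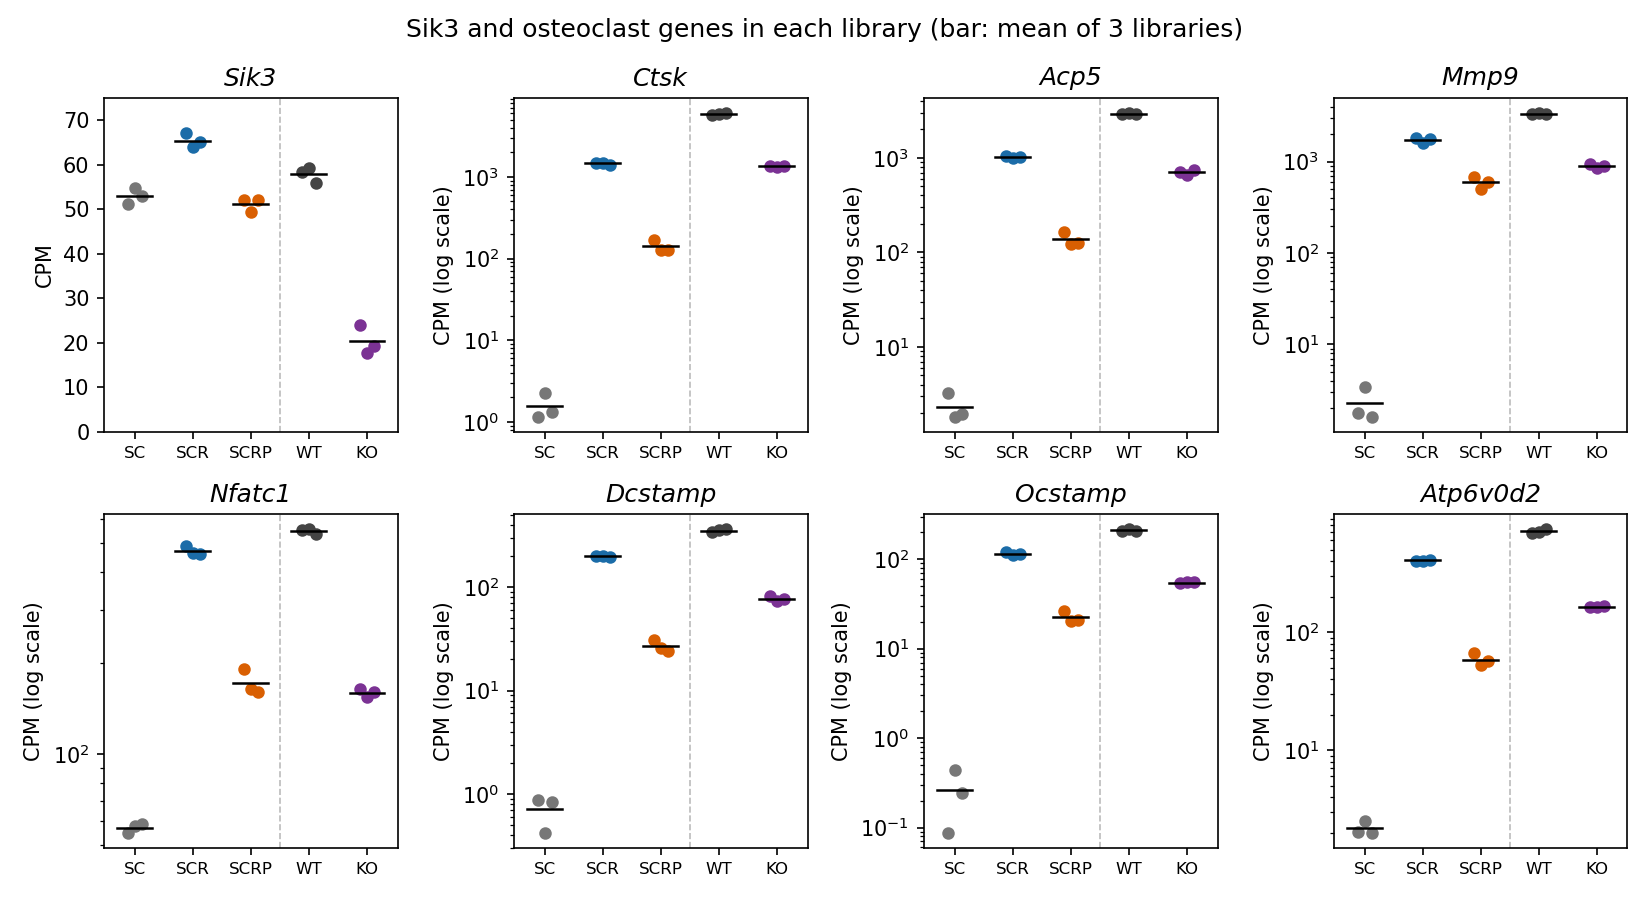
Level of Sik3 (linear axis) and of 7 osteoclast genes (log axes) in CPM for each of the 15 libraries. A bar marks the mean of the 3 libraries of SC, SCR, SCRP, WT and KO. Sik3 averaged 20.3 CPM in KO and 57.9 CPM in WT, and Nfatc1 averaged 159.6 CPM in KO and 547 CPM in WT.

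The comparison of SCR with SC asks which genes differed with RANKL in these precursors. If SC was harvested earlier than SCR, time in culture is part of this difference, here called the RANKL response. The osteoclast genes named here were higher in SCR. Ctsk, the protease that degrades bone collagen (chromosome 3, 95499256 to 95509362), was 946-fold higher in SCR (log2 fold change 9.89, adjusted p = 5.32e-17), with 191 reads over the 3 SC libraries and 201215 over the 3 SCR libraries. Acp5, which encodes tartrate-resistant acid phosphatase, rose from 2.34 ± 0.768 to 1018 ± 16.1 CPM (SD, n = 3), 429-fold, with 69.5% of its reads mapping uniquely. The gelatinase Mmp9 was 764-fold higher. The fusion genes Dcstamp and Ocstamp were 275-fold and 456-fold higher, and Atp6v0d2, a proton pump subunit needed for fusion, was 187-fold higher. Nfatc1, the main transcription factor of osteoclast formation, rose 8.24-fold (log2 fold change 3.04, adjusted p = 1.27e-15).

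Other genes with little or no reading in SC also became abundant. With no SC read and a floor of 3 counts per library, the metallothionein Mt3 was at least 880-fold higher, Rufy4 at least 804-fold, the carbonic anhydrase Car2 at least 701-fold and the calcitonin receptor Calcr at least 123-fold. Oscar, Mst1r, Zfp462, Cyp2s1 and Nyap2 had 2 reads each over the 3 SC libraries and reached 25.9, 54.2, 29.1, 26.9 and 22.1 CPM in SCR. The integrin subunit gene Itgb3 rose 12.5-fold. Src, a kinase required for bone resorption, rose 140-fold, with 136 SC reads. Traf1 was 169-fold higher. Tnfrsf11a, which encodes the RANKL receptor RANK, rose by a log2 fold change of 0.76.

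Macrophage genes fell. The largest falls among named genes averaging at least 8 CPM were Fcrls (48.5-fold), the clotting factor subunit F13a1 (22.6-fold, 60.1% unique reads), the cyclin Ccnd2 (19.9-fold), Gas6 (13.6-fold), Ctla2b (12.9-fold, 35.0% unique reads), the sialic acid receptor Siglec1 (12.6-fold), Wfdc17 (11.3-fold) and the prostaglandin-degrading enzyme Hpgd (11-fold). The complement gene C1qa fell 5.12-fold and the Fc receptor gene Fcgr1 8.66-fold. Irf8, a repressor of osteoclast formation, fell 5.80-fold, although only 45.4% of its reads were unique and it overlaps Gm20388. Csf1r, the M-CSF receptor gene, fell 2.02-fold.

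By fixed list, 22 of 24 osteoclast differentiation genes rose and 2 fell (camera adjusted p = 1.45e-61). Of 21 acid secretion genes, 15 rose and 5 fell (adjusted p = 2.29e-11), and of 13 cell fusion genes, 6 rose and 5 fell (adjusted p = 2.23e-04). All 22 tested monocyte and macrophage genes fell (adjusted p = 1.97e-27). Among 15 anti-osteoclastogenic regulators, 12 fell, Irf8 and the differentiation inhibitor Id1 (9.08-fold) among them, and 3 rose (adjusted p = 4.07e-09). Oxidative phosphorylation and mitochondrial genes rose in 28 of 32 cases, with Idh3a 2.29-fold and Mdh2 1.98-fold higher, and 0 fell (adjusted p = 1.36e-09). Ppargc1b, a coactivator of mitochondrial genes, rose 9.88-fold. These 6 lists also passed with an estimated correlation.

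A further 11 lists passed camera only at the preset correlation. Each passed fry, with adjusted p from 4.50e-07 (p53 and apoptosis) to 0.00277 (interferon response). Fry asks whether a list's genes changed, without comparing them with other genes. It also passed some lists that camera did not, such as cell cycle genes (fry adjusted p = 7.57e-04). All 20 tested cholesterol synthesis genes fell, including Fdps (2.63-fold, 55.5% unique reads) and Sqle (2.18-fold), with adjusted p = 2.68e-07, but adjusted p = 0.257 with an estimated correlation. Lysosome genes fell in 18 of 23 cases, with the cathepsins Ctsb 3.42-fold and Ctsd 3.58-fold lower (36.8% of Ctsd reads unique), at adjusted p = 6.29e-07 and adjusted p = 0.207 with an estimated correlation. NRF2 and oxidative stress genes fell in 15 of 22 cases and rose in 5, with Hmox1 6.02-fold and Fth1 2.19-fold lower, at adjusted p = 9.02e-04 and adjusted p = 0.212 with an estimated correlation. Of 19 NF-kB and inflammation genes, 11 rose, Nfkb2 (5.08-fold) among them, and 5 fell, at adjusted p = 2.39e-04 and adjusted p = 0.0604 with an estimated correlation. Heat shock genes rose in 10 of 12 cases, Hspd1 2.49-fold, at adjusted p = 9.08e-04 and adjusted p = 0.05 with an estimated correlation. Interferon response genes fell in 14 of 22 cases and rose in 1, with Stat2 2.54-fold and Bst2 2.77-fold lower, at adjusted p = 0.0378 and adjusted p = 0.616 with an estimated correlation. Xenobiotic and AHR genes rose in 6 of 12 cases and fell in 2, with Ahr 3.90-fold and its repressor Ahrr 5.56-fold higher, at adjusted p = 0.00883 and adjusted p = 0.0653 with an estimated correlation.

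LXR and lipid handling genes fell in 11 of 16 cases and rose in 2, with the scavenger receptor Cd36 3.96-fold lower (adjusted p = 0.00915, and adjusted p = 0.0877 with an estimated correlation). Of 18 p53 and apoptosis genes, 9 fell and 4 rose (adjusted p = 0.0104, and adjusted p = 0.0653 with an estimated correlation). Of 20 podosome and actin genes, 9 rose and 9 fell (adjusted p = 0.0156 upward, and adjusted p = 0.140 with an estimated correlation). Secreted coupling factors rose in 7 of 10 cases and fell in 3 (adjusted p = 0.0429, and adjusted p = 0.212 with an estimated correlation). The other lists did not pass camera. SIK and CRTC components had 5 rises and 5 falls among 16, with Sik1 3.18-fold higher and Mef2c 4.57-fold, Hdac9 7.75-fold and Mef2a 2.76-fold lower (29.3% of Mef2a reads unique). CREB and CRTC targets had 6 rises, Fos 3.74-fold among them, and 7 falls among 17. Cell cycle genes had 18 rises and 4 falls among 28 (adjusted p = 0.161), glycolysis and hypoxia genes 10 and 7 among 24, unfolded protein and integrated stress genes 10 and 9 among 21, and dendritic cell and MHC class II genes 5 and 4 among 17.

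Of markers of other cell types, neutrophil genes fell in 7 of 13 cases with 0 rises (adjusted p = 0.170), lymphoid genes fell in 1 of 3, erythroid and megakaryocyte genes in 1 of 3, mast cell and basophil genes rose in 1 of 2, and stromal and osteoblast genes rose in 2 and fell in 1 of 9. Adjusted over the list alone, the counts differed for dendritic cell genes (4 rises), stromal genes (1 rise), interferon genes (15 falls), SIK and CRTC components (6 rises, 6 falls), CREB and CRTC targets (8 falls), glycolysis genes (8 falls) and p53 genes (5 rises). The median, the mean and the test of a list differed in sign for 6 of 28 lists: cell fusion, podosome and actin, stromal, CREB and CRTC targets, glycolysis and unfolded protein.

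In all, 8064 of 13650 genes passed (59.1%), 4190 higher and 3874 lower in SCR, and 2333 of them changed at least 2-fold, 1127 higher and 1206 lower. The 3 libraries of each group did not overlap in 65.4% of genes, where chance gives 10%. The strand that was counted is not stated, so reads of genes that overlap another gene cannot be assigned with certainty.

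The comparison of SCRP with SCR asks what pterosin B changed in cultures given RANKL. Osteoclast genes were lower with the compound. Ctsk fell 10.3-fold, to 142 ± 24.2 CPM (SD, n = 3; log2 fold change -3.37, adjusted p = 1.34e-12). Acp5 fell 7.38-fold, from 1018 ± 16.1 to 138 ± 22.8 CPM. Dcstamp fell 7.43-fold, Atp6v0d2 6.93-fold, Itgb3 5.95-fold, Ocstamp 5.10-fold, Mmp9 2.91-fold and Nfatc1 2.74-fold. Calcr fell 28.7-fold. Of genes with roles in resorption, Src fell 3.62-fold, the vesicle sorting gene Snx10 2.81-fold and the proton pump gene Atp6v1b2 2.37-fold.

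The largest falls among named genes averaging at least 8 CPM were Rpph1, the RNA of ribonuclease P (24.7-fold, 79.8% unique reads), Nyap2 (24.3-fold), the neutrophil collagenase gene Mmp8 (20.5-fold, adjusted p = 1.96e-13), the receptor kinase gene Mst1r (16.5-fold), Col27a1 (15.9-fold), Oscar (14.2-fold), the thrombin receptor gene F2r (13.8-fold) and Apbb1 (13.6-fold). The largest rises with the same minimum were Trem1, an amplifier of inflammatory signals in myeloid cells (chromosome 17, 48232768 to 48246924), from 2.85 ± 0.202 to 19.7 ± 0.768 CPM (6.90-fold, adjusted p = 3.31e-10), Syn1 (5.08-fold), which overlaps Timp1 and Araf, Nes (3.97-fold), the chemokine receptor gene Cxcr4 (3.67-fold), the endothelin receptor gene Ednrb (3.50-fold), Ctla2b (3.41-fold, 36.4% unique reads), C1qa (3.15-fold) and C1qb (3.02-fold). Irf8 rose 2.11-fold, with 46.2% unique reads. Csf1r had 1018 ± 28.6 CPM in SCR and 1031 ± 19.8 CPM in SCRP and did not pass (adjusted p = 0.767). Tnfrsf11a was lower by a log2 fold change of -0.13 (adjusted p = 0.0402), but the call was lost when any library other than SCRP replicate 1 was left out, most so without SCRP replicate 2 (-0.09, adjusted p = 0.190).

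**Figure D2:**
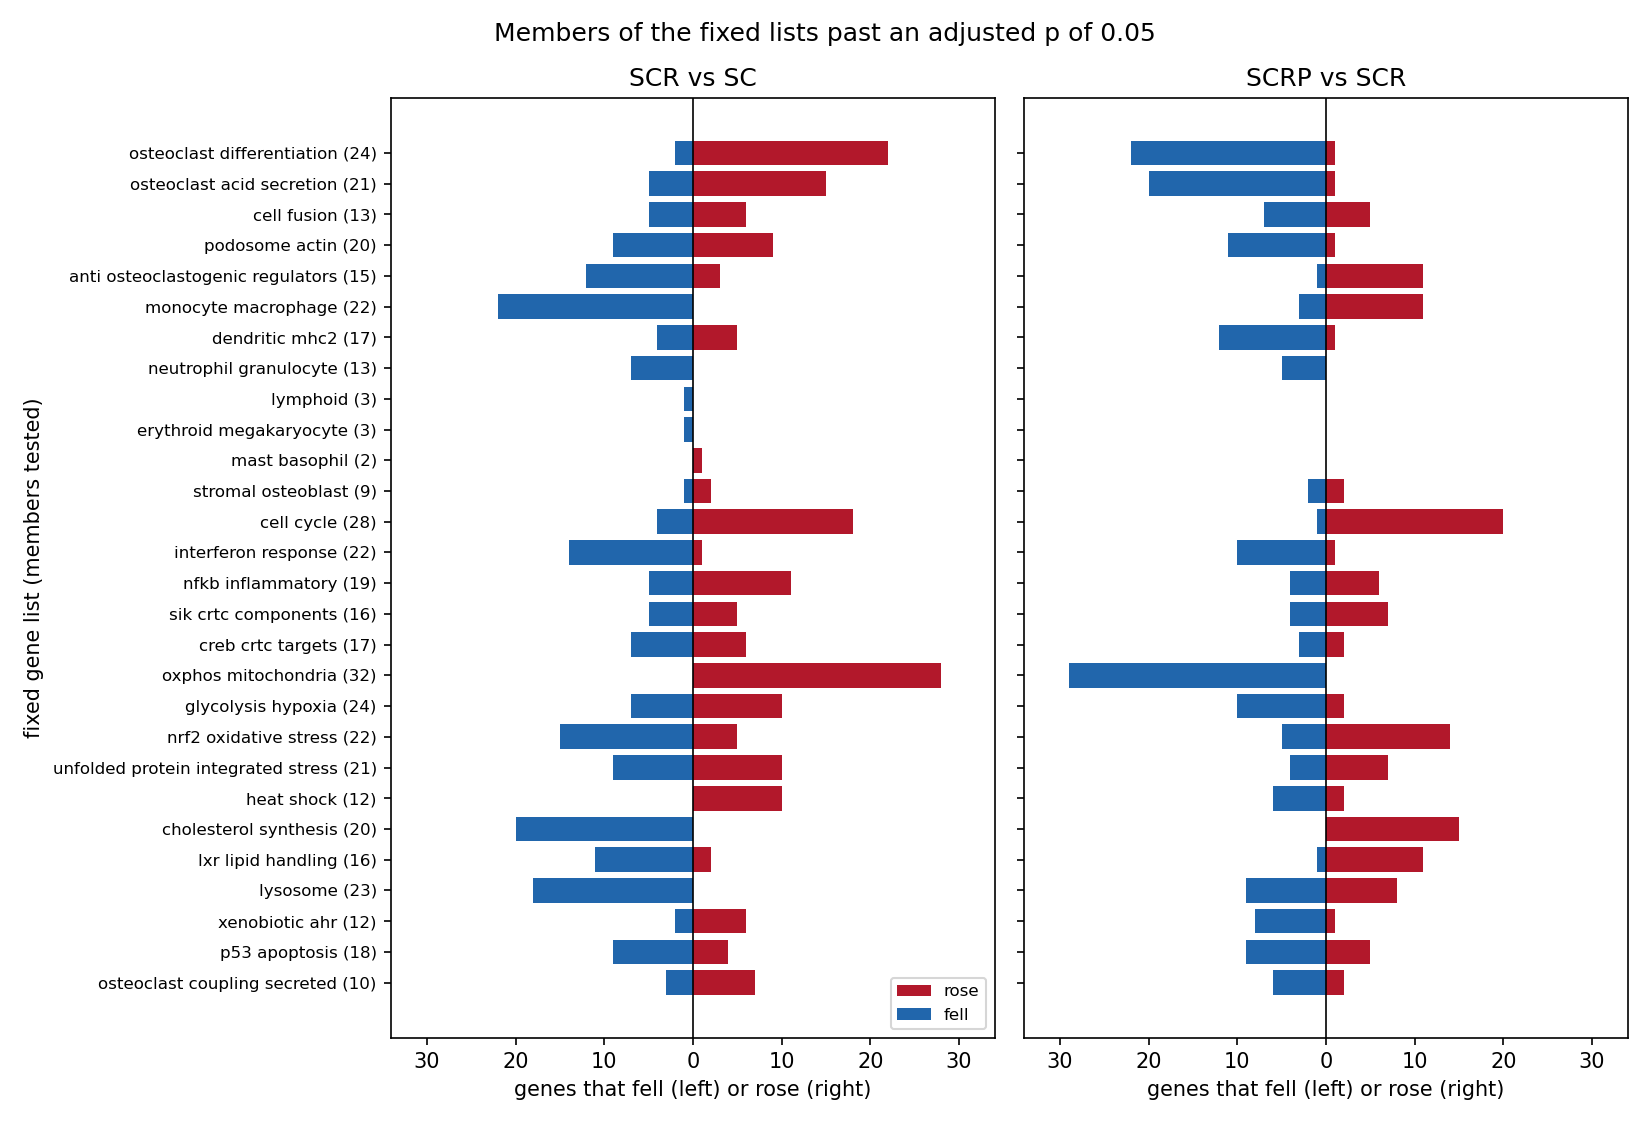
Number of genes of each fixed list that rose or fell at an adjusted p under 0.05, for SCR against SC and for SCRP against SCR. Of 32 oxidative phosphorylation genes, 28 rose with RANKL and 29 fell with pterosin B.

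By fixed list, 22 of 24 osteoclast differentiation genes fell and 1 rose (camera adjusted p = 7.75e-59), and 20 of 21 acid secretion genes fell and 1 rose (adjusted p = 1.90e-48). Of 32 oxidative phosphorylation genes, 29 fell and 0 rose, Atp5b 1.48-fold and Mdh2 1.63-fold lower (adjusted p = 1.67e-19). Cell fusion genes had 7 falls and 5 rises among 13 (adjusted p = 2.54e-05), and podosome and actin genes had 11 falls and 1 rise among 20 (adjusted p = 2.00e-09). Anti-osteoclastogenic regulators rose in 11 of 15 cases and fell in 1 (adjusted p = 1.50e-08). LXR and lipid handling genes rose in 11 of 16 cases, Cd36 2.07-fold, and fell in 1 (adjusted p = 3.01e-04). Xenobiotic and AHR genes fell in 8 of 12 cases and rose in 1 (adjusted p = 1.43e-04). Within that list the receptor gene Ahr rose 2.52-fold, while its repressor and target Ahrr fell 10.8-fold and Cyp2s1 fell 7.30-fold; Nqo1, an NRF2 list member that the receptor also induces, fell 3.59-fold. Neutrophil genes fell in 5 of 13 cases with 0 rises (adjusted p = 7.62e-04). Elane fell from a low level, with 118 reads over the 3 SCR libraries and 2 over the 3 SCRP libraries. Mmp8, also in this list, fell from 37.6 CPM in SCR to 1.84 CPM in SCRP. These 9 lists also passed with an estimated correlation.

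For 6 more lists the camera call was lost with an estimated correlation, while each passed fry (adjusted p from 3.95e-04 to 0.0472). Monocyte and macrophage genes rose in 11 of 22 cases and fell in 3, with the lipopolysaccharide receptor gene Cd14 2.34-fold higher (adjusted p = 1.53e-08, and adjusted p = 0.158 with an estimated correlation). Cholesterol synthesis genes rose in 15 of 20 cases with 0 falls, Fdft1, which overlaps Ctsb, 1.84-fold (adjusted p = 9.11e-06, and adjusted p = 0.373 with an estimated correlation). Cell cycle genes rose in 20 of 28 cases, E2f1 1.35-fold and the replication helicase gene Mcm3 1.27-fold, and fell in 1 (adjusted p = 1.02e-04, and adjusted p = 0.163 with an estimated correlation). Dendritic cell and MHC class II genes fell in 12 of 17 cases and rose in 1, with Cd74 2.88-fold and H2-Ab1 3.67-fold lower (adjusted p = 1.02e-04, and adjusted p = 0.213 with an estimated correlation). NRF2 and oxidative stress genes rose in 14 of 22 cases, G6pdx 1.65-fold (74.2% unique reads), and fell in 5 (adjusted p = 0.00141, and adjusted p = 0.260 with an estimated correlation). Interferon response genes fell in 10 of 22 cases, Oas3 2.53-fold, and rose in 1 (adjusted p = 0.0463, and adjusted p = 0.736 with an estimated correlation). With only SCR and SCRP fitted, this call was also lost, with the replicate block (adjusted p = 0.0664) and without it (adjusted p = 0.0984).

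The other lists did not pass camera. Secreted coupling factors had 6 falls, Lif 15.7-fold and Sphk1 17.5-fold among them, and 2 rises among 10 (adjusted p = 0.157). SIK and CRTC components had 7 rises, Mef2c 1.76-fold and Mef2a 1.24-fold among them, and 4 falls, Sik1 1.68-fold among them, out of 16 (adjusted p = 0.812). NF-kB genes had 6 rises and 4 falls among 19, CREB and CRTC targets 2 and 3 among 17, glycolysis genes 2 and 10 among 24, unfolded protein genes 7 and 4 among 21, heat shock genes 2 and 6 among 12, lysosome genes 8 and 9 among 23, p53 genes 5 and 9 among 18, and stromal genes 2 and 2 among 9. Lymphoid, erythroid and mast cell lists had 0 changes among 3, 3 and 2 tested genes. Adjusted over the list alone, the counts differed for monocyte and macrophage genes (12 rises, 4 falls), cell cycle genes (22 rises), interferon genes (12 falls), SIK and CRTC components (5 falls), unfolded protein genes (5 falls), cholesterol synthesis genes (17 rises), LXR genes (2 falls), lysosome genes (9 rises) and xenobiotic genes (10 falls). The median, the mean and the test of a list differed in sign for 3 lists: stromal, CREB and CRTC targets, and p53.

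In all, 5156 of 13650 genes passed (37.8%), 2439 higher and 2717 lower in SCRP. At least 2-fold changes numbered 819, of which 182 were higher and 637 lower. The groups did not overlap in 49.3% of genes, where chance gives 10%.

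SCRP against SC holds both the RANKL response and the effects of pterosin B, since no group had the compound without RANKL. Each of the 7 osteoclast genes named was still higher than without RANKL. Mmp9 was 263-fold higher, Ctsk 91.7-fold, Ocstamp 89.5-fold, Acp5 58.0-fold, Dcstamp 37.01-fold, Atp6v0d2 26.98-fold and Nfatc1 3.01-fold (adjusted p = 2.69e-12). Of 24 osteoclast differentiation genes, 19 were higher and 4 lower (camera adjusted p = 2.97e-36, and adjusted p = 0.0531 with an estimated correlation). All 22 monocyte and macrophage genes were lower (adjusted p = 1.03e-20, and adjusted p = 0.0531 with an estimated correlation). Of 21 acid secretion genes, 6 were higher and 11 lower (adjusted p = 0.829), and of 20 podosome and actin genes, 7 were higher and 10 lower (adjusted p = 0.734). Neutrophil genes were lower in 11 of 13 cases and higher in 0 (adjusted p = 4.32e-04, and adjusted p = 0.0531 with an estimated correlation). Interferon response genes were lower in 20 of 22 cases and higher in 1 (adjusted p = 2.40e-04, and adjusted p = 0.485 with an estimated correlation), and cell cycle genes were higher in 25 of 28 and lower in 2 (adjusted p = 4.24e-05, and adjusted p = 0.172 with an estimated correlation). Camera called 13 of 28 lists, 5 upward and 8 downward, and 0 lists passed camera with an estimated correlation. The 13 lists all passed fry (adjusted p from 8.02e-07 to 0.00188). Adjusted over the list alone, counts differed for cell fusion (6 falls), erythroid (1 rise), cholesterol synthesis (19 falls) and LXR genes (2 rises), and 11 lists had a median, mean and test that differed in sign. In all, 7639 of 13650 genes passed, 3904 higher and 3735 lower, of which 1854 changed at least 2-fold, 775 higher and 1079 lower. The groups did not overlap in 61.5% of genes, where chance gives 10%.

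Genes that RANKL had moved were set against their response to pterosin B. Of 4190 genes raised by RANKL, 1745 (41.6%) were lowered by pterosin B, where 834 would be by chance, and 322 (7.7%) were raised further, where 749 would be by chance. Of 3874 genes lowered by RANKL, 1501 (38.7%) were raised by pterosin B, where 692 would be by chance, and 424 (10.9%) were lowered further, where 771 would be by chance. Among genes moved at least 2-fold by RANKL, the opposite call was made for 645 of 1127 raised genes (57.2%) and 551 of 1206 lowered genes (45.7%). Of the 1127 raised and 1206 lowered genes, 831 and 1051 still differed between SCRP and SC. Across the 13650 genes, which are not independent replicates, Pearson's r was -0.556 and Spearman's rho -0.462. Both responses use the SCR libraries, and 100 simulations of unchanged groups gave a mean r of -0.5 with a lowest of -0.553. With 1 library left out the measured r was -0.595 to -0.505, which reaches into the range of unchanged groups. The covariance was -0.558 against a simulated mean of -0.052, and at most 1 gene was called in opposite directions in any of 20 simulated refits. No gene was changed in these refits, so they cannot show how far shared SCR error adds opposite calls among genes that RANKL moved. The counts by chance take both calls as independent, which the shared SCR libraries do not allow.

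The comparison of KO with WT asks which genes differ when Sik3 is deleted in RANKL-treated cultures. The study chose the listed genes on these samples, so neither the counts nor the p-values of single genes are independent evidence of a difference. Adjustment over the listed genes alone does not hold the false discovery rate, and such a choice can make SE values too small. Osteoclast genes were lower in KO. Ctsk fell from 5888 ± 161 to 1349 ± 36.4 CPM (SD, n = 3), 4.36-fold (log2 fold change -2.13, adjusted p = 9.32e-23 by edgeR quasi-likelihood with Benjamini-Hochberg adjustment). Acp5 fell 4.15-fold, Mmp9 3.72-fold, Nfatc1 3.43-fold, Dcstamp 4.56-fold, Ocstamp 3.84-fold, Atp6v0d2 4.33-fold, Oscar 4.31-fold and Itgb3 2.64-fold. Tnfrsf11a, whose locus carries the Cre allele, fell from 276 ± 3.34 to 102 ± 4.70 CPM, 2.70-fold (adjusted p = 2.18e-18).

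Macrophage genes were higher in KO. Mrc1, the mannose receptor gene, rose 10.8-fold, C1qa 7.71-fold, C1qc 6.19-fold, and the chemokine gene Ccl2 5.33-fold. The largest rises among named genes averaging at least 8 CPM were Pianp (161-fold, with 9 reads over the 3 WT libraries), the ribosomal protein gene Rps18 (54.2-fold), Fcrls (39.6-fold), H2-T22 (21.8-fold), F13a1 (17.4-fold), the formyl peptide receptor gene Fpr1 (15.3-fold), Cbr2 (14.3-fold) and the cholesterol 25-hydroxylase gene Ch25h (13.8-fold). The largest falls with the same minimum were Ptchd1 (14.7-fold), the heat shock gene Hspa1b (10.5-fold), Efr3b (9.11-fold), Calcr (7.94-fold), the peptide-processing enzyme gene Cpe (6.99-fold), the collagen gene Col4a5 (6.17-fold), the lipoprotein lipase gene Lpl (5.78-fold) and Zfp462 (5.65-fold). Hspa1a, which averaged less, fell 6.20-fold. Rps18, H2-T22, Hspa1a, Hspa1b and Tnf lie between 33 and 38 Mb of chromosome 17, where 9 of 9 listed genes at least 8-fold apart had an SCR level nearer to KO than to WT. Rps18 also has a near-identical copy, Gm10260, that took 388 CPM in WT and 0.0856 CPM in KO.

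By fixed list, 19 of 24 osteoclast differentiation genes were in the table, 0 higher and 19 lower (Fisher exact adjusted p = 9.96e-05). Of 23 monocyte and macrophage genes, 16 were listed, all higher (adjusted p = 9.96e-05). Interferon response genes were listed 11 times, all higher, with Stat2 2.58-fold and Bst2 2.64-fold (adjusted p = 0.00183). The KO libraries were uneven for them: the median SD in KO was 25% of the mean, against 6.77% for all genes higher in KO, and 10 of the 11 were highest in KO replicate 3. All 11 passed without that library. Anti-osteoclastogenic regulators were listed 8 times, all higher, with Irf8 3.41-fold and Id1 5.02-fold (adjusted p = 0.0140). These 4 lists passed, and the others did not. The Fisher test counts members as the authors listed them, some of which were too low to test here. Neutrophil genes had 6 members listed as higher, of which 5 were tested and rose, and 0 as lower (adjusted p = 0.0527). Podosome and actin genes had 6 falls and 0 rises (adjusted p = 0.151), with Src 3.42-fold, Cttn 3.80-fold and Itgav 2.37-fold lower. Cholesterol synthesis genes, Fdps 2.31-fold among them, and lysosome genes, Ctsb 2.37-fold and Ctsd 2.27-fold among them, each had 4 rises and 0 falls (adjusted p = 0.154).

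NF-kB genes had 5 rises, Ccl2 and Tnf (3.52-fold) among them, and 1 fall (adjusted p = 0.250). Acid secretion genes had 1 rise, Atp6v0a1 2.87-fold, and 5 falls, Atp6v1b2 2.48-fold among them (adjusted p = 0.489). SIK and CRTC components had 3 rises, Mef2a 2.19-fold and Mef2c 2.65-fold among them, and 2 falls, Sik1 2.75-fold and Sik3 itself (adjusted p = 0.819). LXR genes had 2 rises, Apoe 3.46-fold among them, and 2 falls, Lpl among them. Secreted coupling factors had 2 rises and 6 falls (adjusted p = 0.538), and Spp1, the osteopontin gene, was 3.25-fold higher. Unfolded protein and integrated stress genes had 0 rises and 3 falls, with the serine and asparagine synthesis genes Phgdh 3.63-fold and Asns 2.96-fold lower (adjusted p = 0.489). Ppargc1b, in the mitochondrial list, was 3.47-fold lower and the only listed member. Among tested members, xenobiotic genes had 1 rise and 4 falls, cell fusion genes 3 and 3, p53 genes 3, the survival gene Bcl2l1 (3.998-fold) among them, and 2, dendritic cell genes 2 and 1, NRF2 genes 1 and 0, and mast cell and glycolysis genes 0 and 1 each. Lymphoid genes had 1 rise and 0 falls, erythroid genes 2 and 0, heat shock genes 0 and 2, and CREB and CRTC targets and stromal genes 0 and 1 each. The authors list 3 lymphoid and 3 erythroid genes and 2 CREB and CRTC targets as higher, and 3 heat shock, 4 cell fusion, 2 stromal and 1 CREB and CRTC gene as lower. None of the 28 cell cycle genes was listed. Adjusted over the list alone, the counts of tested members were unchanged, which is not independent evidence in a table chosen this way.

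In all, 1765 of 1773 tested genes passed, 856 higher and 909 lower in KO, and 1718 changed at least 2-fold. The groups did not overlap in 97.5% of genes, which were chosen for differing between these libraries. The table holds no genes that failed the authors' thresholds, so shares of all genes cannot be given, and the labels do not say whether WT carried Cre.

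**Figure D3:**
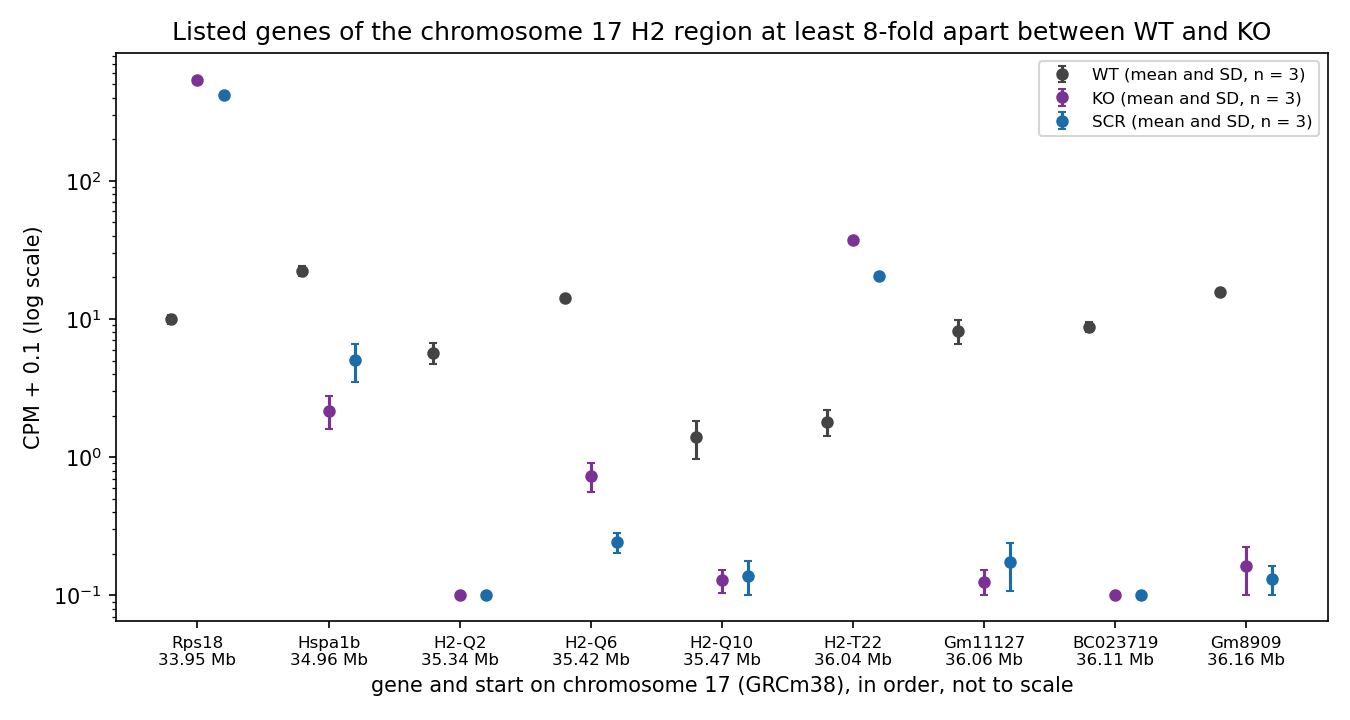
Level in CPM (log axis, 0.1 added) of the 9 listed genes between 33 and 38 Mb of chromosome 17 that differ at least 8-fold between WT and KO, as mean and SD of 3 libraries in WT, KO and SCR, with all libraries scaled to the totals implied by RPKM. H2-T22 averaged 1.71 CPM in WT, 37.3 CPM in KO and 20.4 CPM in SCR.

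The comparison of the KO and pterosin B responses asks whether deletion and compound moved genes in the same direction. It covers 1667 listed genes tested in both experiments. These had been chosen for a change in KO, so the Fisher tests here compare directions and cannot show whether the same genes changed. Among genes higher in KO, 371 also rose with pterosin B, where 195 would be by chance (Fisher exact p = 1.10e-105), and 79 fell. Among genes lower in KO, 494 also fell with pterosin B, where 286 would be by chance (Fisher exact p = 2.57e-110), and 21 rose. Ctsk, Acp5, Nfatc1, Calcr and Src were lower in both, while C1qa, Irf8 and Mef2c were higher in both. F13a1 and Mmp8 rose in KO, by log2 fold changes of 4.12 and 1.26, and were lower with pterosin B, by -1.29 and -4.36. Pearson's r across these genes was 0.548 and Spearman's rho 0.617, and the genes are not independent replicates. All were chosen for a KO change of at least 2-fold, which can make a correlation stronger than over all genes. At least 2-fold changes in the same direction in both numbered 440, out of 865 called in the same direction without a minimum fold.

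The KO response was also set against the RANKL response. Across the 1667 genes, Pearson's r was -0.711 and Spearman's rho -0.822. The choice of genes by their KO change can strengthen these values too. Of genes higher in KO, 688 had been lowered by RANKL and 17 raised. Of genes lower in KO, 638 had been raised by RANKL and 14 lowered. With the RANKL response held fixed, the partial Spearman correlation of KO and pterosin B was 0.096. Among 308 listed genes without a RANKL call, rho was 0.081 (permutation p = 0.15, 10000 permutations), and 51 of them were called with pterosin B, 34 in the direction of KO and 17 against it (exact binomial p = 0.0241, two-sided).

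**Figure D4:**
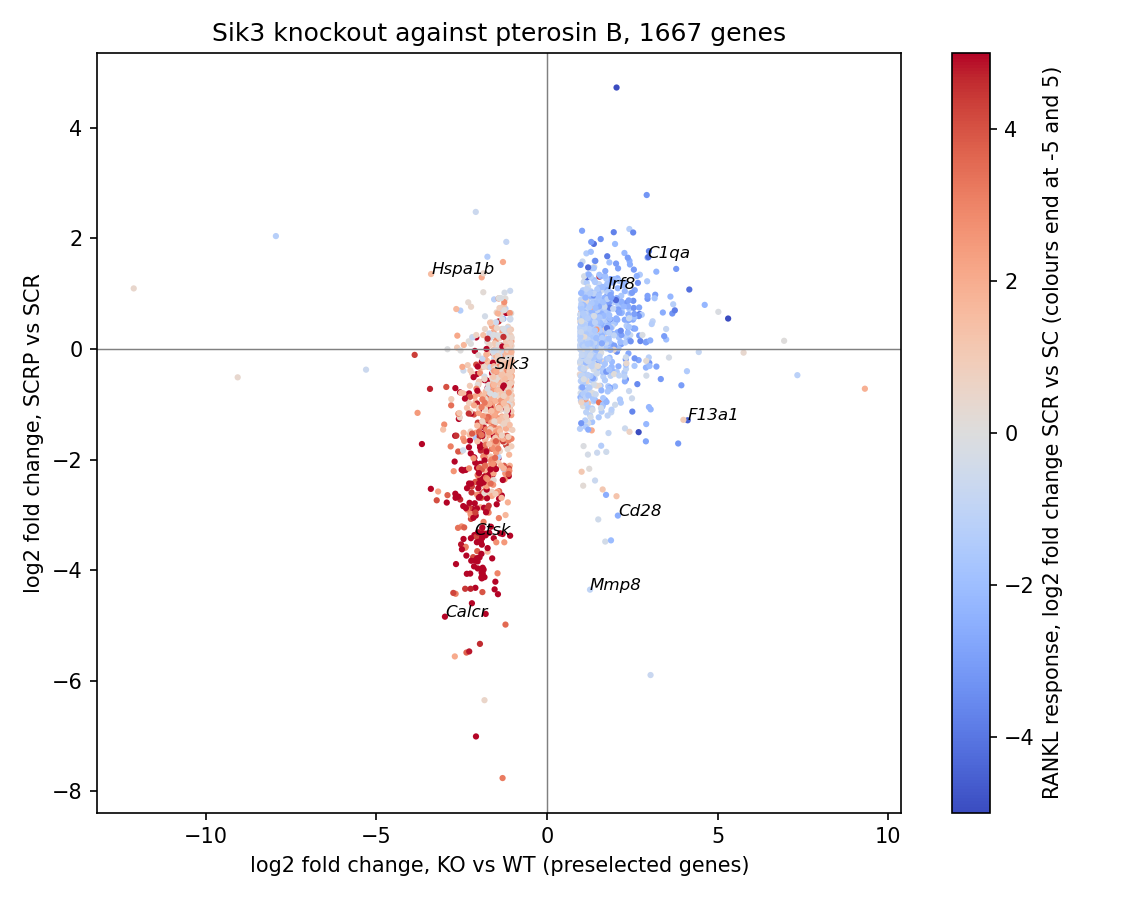
Log2 fold change in KO against WT (horizontal axis) and in SCRP against SCR (vertical axis) for 1667 listed genes, each point coloured by its log2 fold change in SCR against SC. Genes higher in KO were mostly those lowered by RANKL, and r was 0.548.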

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

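All tests of an explanation in this part, and all counts of splits, were chosen after the results had been seen.

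With 3 libraries against 3 there are 10 ways to split 6 libraries, so the share of splits with as many edgeR calls is never under 0.1. For SCR against SC, 1 of the 10 splits, the real split, gave 8064 genes or more, and the highest other split gave 0. For SCRP against SCR, 1 split gave 5271 genes or more, and the highest other gave 0. Of its 4 splits that part every pair of the same replicate number, the real split gave 5805 genes with the replicate block, and the others gave 0. For SCRP against SC, 1 split gave 7435 genes or more, and the highest other gave 0. For KO against WT, 1 split gave 1765 genes or more and the highest other gave 1, but the listed genes had been chosen on the real split, so this is not evidence of a difference. These fits use only the libraries of the groups compared. Every other split mixes the groups, so a large difference between them widens the spread and few calls can follow. The low counts of the other splits therefore do not measure how many calls arise without a difference.

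Among intron reads, which no comparison above uses, Cep85 (chromosome 4, 134129858 to 134187112) ranked 1 by its total. Cep85 had 1137 ± 101 intron CPM, scaled to exon totals, in SC, 2049 ± 145 in SCR and 5043 ± 551 in SCRP (SD, n = 3). Its intron log2 fold change was 2.06 in SCRP against SC (adjusted p = 8.43e-19 by edgeR) and its exon log2 fold change 1.81. The annotation places the snoRNA Gm27619 (134167808 to 134167895) inside the gene.

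Of the 9 listed genes between 33 and 38 Mb of chromosome 17, which holds H2 genes, that lay at least 8-fold apart between WT and KO, 100% had an SCR level nearer to KO than to WT, against 25% of 28 such genes elsewhere (Fisher exact p = 9.20e-05), so a strain or haplotype variant carried by the WT cultures is a candidate explanation, although the labels give C57BL/6J for all. Over all listed genes the contrast was smaller, with 29 of 45 genes of the region (64.4%) nearer to KO against 32.9% elsewhere. For Rps18, reads shared with its copy Gm10260 (98.8% identity over 403 bases) may add to this, since the sum of both differed only 1.34-fold between KO and WT, against 54.2-fold for Rps18 alone. Loss of SIK3 is unlikely as the reason for 6 genes of the region that had at least 1 CPM in WT and under 10% of that in both KO and SCR, which has an intact Sik3 (2 such genes among 2202 elsewhere, Fisher exact p = 1.25e-09). Genotypes and read sequences were not used here, so a variant was not tested directly. Nor was it tested whether a difference in background reaches beyond this region, so other differences between KO and WT could also reflect it.

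The lower osteoclast genes and higher macrophage genes of KO may reflect cultures less far along the RANKL response: across listed genes, the KO and RANKL log2 fold changes had a Spearman correlation of -0.822. That test cannot tell slower differentiation from a direct effect on the same genes or from cultures that started with other cells. Its genes were also chosen for their KO change, which can strengthen a correlation. A smaller number of intact Tnfrsf11a copies, with Cre in that locus, could also lower RANKL signalling. Tnfrsf11a fell in KO by more than a whole reversal of its RANKL response (difference -0.668 ± 0.064, SE), but this stays open because the labels do not say whether WT carried Cre. Library depth is unlikely as a source, with a KO to WT ratio of mean library totals of 1.03.

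The correlation of the KO and pterosin B responses could arise because each opposes the RANKL response. The Spearman correlation of 0.617 became 0.096 once the RANKL log2 fold change was held fixed. This drop cannot tell a shared reversal of that response from an effect of SIK3 through it, since holding it fixed removes both. The RANKL and pterosin B responses also share the SCR libraries, so shared error enters the value of 0.096. Among 308 genes without a RANKL call, rho was 0.081 (permutation p = 0.15), while 34 were called with pterosin B in the direction of KO and 17 against it (exact binomial p = 0.0241). Both tests take genes as independent, and they differ. Genes without a RANKL call may still have responded below the threshold, and the SCR libraries enter both that choice and the pterosin B response. A link of the compound to Sik3 beyond that reversal therefore stays open. The chromosome 17 region is unlikely as a source, since Pearson's r was 0.566 without it. The experiments also differ in plate, cell number and days of RANKL, whose effects were not tested.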

How the results depend on the processing

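Halved counts, unique reads, TMM over the listed genes, removal of the chromosome 17 region, a paired fit of only SCR and SCRP, left-out libraries for correlations, and the alternatives for KO against RANKL were chosen after the values had been seen, and the rest were planned. Counts of called genes stayed within 1.5 times of the main count under every alternative except, in the pterosin B experiment, a minimum fold: 7567 to 8182 for SCR against SC, 4396 to 5805 for SCRP against SCR, 7039 to 7773 for SCRP against SC, and 1713 to 2217 for KO against WT. A minimum fold of 2, which by its construction keeps fewer genes, gave 2333, 819 and 1854 genes in the pterosin B experiment, and 440 of the 865 genes called in the same direction in KO and with pterosin B. An estimated list correlation left 6 of 17, 9 of 15 and 0 of 13 called lists for SCR against SC, SCRP against SCR and SCRP against SC. For correlations, r of KO with pterosin B was 0.694 at a mean of at least 8 CPM, 0.566 without the chromosome 17 region and 0.503 to 0.552 with 1 library left out; the cause was not tested. For KO with RANKL, r was -0.806, -0.724 and -0.713 to -0.695 under the same changes, and r of RANKL with pterosin B was -0.595 to -0.505 with 1 library left out; the cause was not tested. DESeq2 size factors, taken over the preselected genes, moved the median log2 fold change of KO against WT by 0.34, and TMM over them by 0.01. Sik3 in KO had a log2 fold change of -1.18 with those size factors and -1.42 at the weakest with 1 library left out, and passed in each.

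With the replicate number as a replicate block, 8182, 5394, 7773 and 1757 genes passed for SCR against SC, SCRP against SCR, SCRP against SC and KO against WT, among them 98.9%, 98.4%, 98.8% and 99.3% of those passing without it. The numbers may pair SCR with SCRP, which was not established, and gave no such sign in the other comparisons. For WT with KO, the correlations at the same number lay below those of the other pairs. Correlations between libraries of the same number were -0.064 to 0.105 for SC with SCR, -0.108 to 0.314 for SC with SCRP and -0.242 to -0.107 for WT with KO, against -0.078 to 0.124, -0.332 to 0.227 and -0.032 to 0.186 for other pairs. With only SCR and SCRP fitted and the replicate block, 5805 genes passed, among them 97.8% of those passing in the fit of all groups. That fit ended the camera call of interferon genes (adjusted p = 0.0664), as did the same fit without the block (adjusted p = 0.0984). It changed no other call among the 28 lists and 56 named genes of SCRP against SCR. In the fit of all groups, the block ended the camera call of secreted coupling factors in SCR against SC (adjusted p = 0.243) and of dendritic cell genes in SCRP against SC (adjusted p = 0.0764), and it added NRF2 genes in SCRP against SC (adjusted p = 0.0368). Of 173 named results, all kept direction and side of the threshold under the block, DESeq2 size factors and the DESeq2 Wald test, and 172 did so with each library left out. The exception was Tnfrsf11a in SCRP against SCR, with adjusted p = 0.138, 0.0744 and 0.0656 without SCR replicates 1, 2 and 3, 0.190 and 0.0829 without SCRP replicates 2 and 3, and 0.0169 without SCRP replicate 1. The low-count filter left 502 listed genes of the knockout table and 28169 genes of the full table untested, 21653 of the latter with no read in any library.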

Other observations

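The genes and the tests in this part were chosen after their values had been seen. Pterosin B did not only oppose RANKL. Among genes averaging at least 8 CPM in SCRP or over SC and SCR, 15 fell at least 2-fold with RANKL and again at least 2-fold with pterosin B. The collagenase gene Mmp8 went from 75.4 ± 3.74 CPM in SC to 37.6 ± 4.69 in SCR and 1.84 ± 0.189 in SCRP (SD, n = 3). The costimulatory receptor gene Cd28 went from 49.1 to 8.42 and 1.05 CPM, and Siglec1 from 236 to 18.7 and 8.57 CPM. A further 6 genes rose at both steps: the cytokine signalling inhibitor Socs3 from 4.09 to 8.51 and 17.3 CPM, the phospholipid transfer protein gene Pltp from 11.7 to 59.2 and 136 CPM, the complement regulator gene Cd55, Ahr, Hspa1b and Chst7.

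Some genes moved in opposite directions in KO and with pterosin B. Mmp8 rose in KO by a log2 fold change of 1.26 and was lower with pterosin B by -4.36. Cd28 had 2.08 and -3.02, and Cbr2 3.84 and -1.71. The stem cell antigen gene Ly6a went from 7.41 ± 1.36 CPM in WT to 20.8 ± 6.28 in KO (SD, n = 3), and from 4.29 CPM in SCR to 0.502 in SCRP. The interferon-inducible genes Oasl2, Rtp4, Ifi209 and Ifi27l2a also rose in KO and fell with pterosin B. Their KO libraries were uneven, at 21.2 ± 8.65, 19.3 ± 8.55, 12.7 ± 2.84 and 27.9 ± 9.2 CPM in that order (SD, n = 3). Of the 11 interferon list members higher in KO, 3 fell and 1 rose with pterosin B. Phgdh, an enzyme of serine synthesis, had -1.86 in KO and 1.37 with pterosin B.

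Intron reads of the same libraries gave another measure of each comparison, which is not independent of the exon reads. By edgeR quasi-likelihood, 4007 of 12665 genes passed for SCR against SC, 1780 for SCRP against SCR and 3548 for SCRP against SC. Of genes called by both intron and exon reads, 98.8%, 99.2% and 98.7% had the same direction. Over all 11580 genes tested with both, Pearson's r of the intron and exon log2 fold changes was 0.859, 0.68 and 0.797, in the same order.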
